A study of Mus musculus with 60 samples.

How the data were processed

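Balb/c 3T3 mouse embryo fibroblasts were seeded at low density, treated at 60 to 65% confluence and kept in 0.75% DMSO as controls, per the labels' protocols. RNA was labelled with biotin and hybridised to single-colour oligonucleotide arrays of 1 design, and GCOS is named in the submitters' processing notes without a version. Background correction, probe set summarization and the scaling target were not given in the sources used here. The deposited values are 1 intensity on a linear scale for each of 45101 probe sets on each of 60 arrays. The 2 approaches had been scaled differently before deposit. The mean intensity after trimming 2% at each end was 499.84 to 499.87 on the 30 arrays of approach 2 and 152.86 to 187.51 on those of approach 1, and the highest intensities were 30046 to 46363 and 10633 to 12235. Levels and responses were therefore not tested across approaches, and 7 comparisons that would have needed it were left out.

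Groups, comparisons, tests, gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. Probe sets were named through the platform's gene table, with symbols updated by gene identifier where a current table held it (204 probe sets without a match kept the old symbol). Of the probe sets, 34958 had 1 gene symbol, 932 had several and were left out, and 9211 were unlisted and stay unnamed. Each of the 18194 symbols was represented by its probe set with the highest mean, and a gene was tested when that probe set lay above the median of all probe sets in at least 3 arrays, which left 12637 genes. Values were log2(intensity + 16), so a fold change of a dim gene is understated. The array medians of log2 spanned 1.006 over the 60 arrays, which by the preset rule called for quantile normalization. It was run within each approach, a choice made after the 2 scalings were seen, and normalization over all 60 arrays is among the alternatives.

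All 60 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) of 20 group means with 40 residual degrees of freedom, followed by moderated tests with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over genes within each comparison and a threshold of 0.05. Each treatment was compared with the DMSO controls of its approach and time, BaP with MCA at each time, 120 h with 24 h in the controls, and the 120 h response with the 24 h response where the concentration was the same. That made 27 comparisons. Intervals are 95% limits of a log2 difference, from the spread shared by all 60 arrays.

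Because spread differed between the approaches, the shared fit was tested on simulated data. With 200 genes changed by 1.5-fold, 2-fold or 4-fold among the 12637 and 1 spread for all arrays, 31.9% to 69.4%, 64.4% to 91.1% and 94.4% to 100% of the changed genes were recovered over the comparisons, with 3 to 18 unchanged genes called. With each approach's own spread, the shared fit called 0 to 4 unchanged genes in approach 1 and 95 to 150 in approach 2, against 1 to 13 and 3 to 13 for separate fits. It recovered 130 to 172 of the 200 in approach 1 against 171 to 194 for separate fits, and 138 to 178 against 109 to 157 in approach 2. In this simulation counts of approach 2 from the shared fit held more false calls than the threshold states. Separate fits were added after this was seen. Wrong groupings of approach 2 treatments called at most 17 genes with all 3 same-numbered pairs parted and up to 1475 with 1 parted. These put treatment effects into the spread and cannot measure the excess, whose size in the real counts stays open. The genes named by the rule that lost their call in a separate fit numbered 0 in each treatment of approach 1, and in approach 2 they were 11 of 14, 16 of 61, 14 of 76 and 25 of 53 for AAF, BaP, DAT and MCA at 24 h, and 31 of 47, 14 of 38, 7 of 7 and 10 of 42 at 120 h.

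The labels number the arrays of each group 1 to 3. Whether a number pairs arrays was checked by the correlation, across genes, of their deviations from group means. It averaged 0.363 and 0.241 for arrays with the same number at 24 h and 120 h in approach 1 and 0.290 and 0.316 in approach 2, and -0.177, -0.117, -0.145 and -0.158 for other numbers. In 16 of 22 comparisons all 3 pairs passed 0.1, and there the count with the replicate number as a block is given where it moved by over 1.5 times. The pairing is read from the data, since the labels do not say what a number shares.

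The 23 gene lists covered the aryl hydrocarbon receptor battery, other xenobiotic enzymes, Nrf2 and oxidative stress, p53 targets, DNA repair, the stress response of the endoplasmic reticulum and Atf4, heat shock, cholesterol synthesis, mitosis, DNA replication, growth arrest, immediate early genes, extracellular matrix, matrix proteases, interferon, inflammation, hypoxia and glycolysis, smooth muscle, adipocyte, epithelial, endothelial and macrophage markers and placental prolactins. For 22 of them camera tested the list against all other genes with a preset correlation of 0.01 and with an estimated one, adjusted over lists and comparisons of a kind. Of the 162 list calls 87 held with the estimated correlation.

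The genes named were the 6 largest rises and falls of each treatment whose 3 arrays all lay beyond the 3 of the other group (4 in the other comparisons), passing over clone names, then up to 4 called members of each list with at least 3 called, and Cyp1a1, Cyp1b1, Tiparp, Nqo1, Cdkn1a, Mdm2 and Ccng1. Together the rule named 878 values that passed. The text gives 189 of them, picked after their values were seen and in part because their calls held in leave-outs and separate fits, so they are more stable than the whole. Of the 878, 207 lost their call in some leave-out and 147 in a separate fit (70 and 0 of 439 in approach 1, 137 and 147 of 439 in approach 2). The 3'/5' ratios of Gapdh and actin are given, as mean ± SD in log2 units, where all 3 arrays of a group lay beyond the other 3 or, in paired comparisons, all 3 pairs moved the same way, a choice made after the values were seen. Alternatives were a pseudocount of 1, no filter, deposited values without normalization, the replicate block, a fit of the arrays of a comparison alone and leaving out each array in turn. Normalization over all 60 arrays, separate fits and leaving out 3 arrays that stand apart were added after the data were seen.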

Results

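RNA from Balb/c 3T3 cells, an established line of mouse embryo fibroblasts that stops dividing when crowded, was measured on 60 single-colour oligonucleotide arrays with 45101 probe sets each. The cells had been treated with one of 4 chemicals or with the solvent DMSO alone. The chemicals were the aromatic amides and amines 2-acetylaminofluorene (AAF) and 2,4-diaminotoluene (DAT) and the polycyclic aromatic hydrocarbons benzo(a)pyrene (BaP) and 3-methylcholanthrene (MCA). In a first set, here approach 1, literature concentrations of 25 µM AAF, 0.5 µM BaP, 50 µM DAT and 2 µM MCA were given for 24 h and for 120 h. In a second set, approach 2, concentrations meant to inhibit growth by a fixed small share (IC20) were given, which were 10 µM AAF, 1.5 µM BaP, 700 µM DAT and 20 µM MCA for 24 h and 10 µM AAF, 0.1 µM BaP, 0.2 µM DAT and 0.1 µM MCA for 120 h. Each approach had its own DMSO controls at each time, which made 20 groups of 3 arrays. The labels call each experiment triplicate and do not say whether the 3 were separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

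The median deposited intensity of an array lay between 41.2 and 47.1 in approach 1 and between 56.3 and 98.9 in approach 2. The mean correlation of an array with the others of its group was 0.983 to 0.996 in approach 1 and 0.980 to 0.986 in approach 2. The median residual SD of a gene was 0.114 log2 units in approach 1 and 0.218 in approach 2. All 60 arrays shared 1 estimate of the spread, so counts of genes in approach 1 came out lower, and in approach 2 higher, than in a fit of each approach alone, and both counts are given below. Log2 changes are treated minus control ± SE with n = 3 arrays per group. The genes given as rising or falling in a comparison passed an adjusted p of 0.05 over the 12637 genes tested, and the highest adjusted p among the genes named is given. For those given as the largest rises or falls, all 3 arrays of one group lay beyond all 3 of the other.

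The DMSO controls were compared between 24 h and 120 h to see how the cells changed in culture without a chemical. Genes of cell division fell over time. Of the mitosis list in approach 1, 29 of 29 fell (29 adjusted over the list alone), with a median of -2.24 and a camera adjusted p = 5.32e-40. In approach 2, 29 of 29 fell (29 adjusted over the list alone), with a median of -1.77 and a camera adjusted p = 9.76e-29. Examples in approach 1 were the checkpoint kinase Bub1 at -2.71 ± 0.10, the kinase Aurkb at -2.49 ± 0.14 and the replication licensing factor Cdc6 at -2.94 ± 0.18, with -2.20 ± 0.14 for Aurkb and -2.70 ± 0.18 for Cdc6 in approach 2. In the DNA replication list, 30 of 30 fell (30 adjusted over the list alone), with a median of -1.95 and a camera adjusted p = 2.5e-32 in approach 1, and 30 of 30 fell (30 adjusted over the list alone), with a median of -1.64 and a camera adjusted p = 6.18e-25 in approach 2. Sterol synthesis genes fell as well. In the cholesterol synthesis list, 18 of 20 fell (18 adjusted over the list alone), with a median of -1.58 and a camera adjusted p = 6.74e-17 in approach 1, and 18 of 20 fell (18 adjusted over the list alone), with a median of -1.30 and a camera adjusted p = 4.68e-13 in approach 2. The isomerase Idi1 changed by -3.00 ± 0.18 and -2.88 ± 0.18 in approaches 1 and 2, and Fdps, which makes farnesyl diphosphate, by -2.95 ± 0.27 and -2.55 ± 0.27. Among these genes the highest adjusted p was 7.4e-13 in approach 1 and 5.44e-11 in approach 2.

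Matrix genes rose in the controls over the same time. In the extracellular matrix list, 25 of 29 rose (26 adjusted over the list alone), with a median of 0.89 and a camera adjusted p = 1.26e-13 in approach 1, and 23 of 29 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 0.81 and a camera adjusted p = 2.37e-11 in approach 2. The matricellular protein periostin (Postn) rose by 3.17 ± 0.20 and 1.76 ± 0.20 in approaches 1 and 2, tenascin C (Tnc) by 2.17 ± 0.14 and 2.19 ± 0.14, and angiotensinogen (Agt) by 3.72 ± 0.38 and 4.11 ± 0.38. In the smooth muscle list of approach 1, 6 of 9 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.87 and a camera adjusted p = 0.000219. The matrix protease list had 10 members rising and 3 falling of 15 in approach 1 and 9 rising and 3 falling in approach 2 (10 and 3 in each adjusted over the list alone), with camera adjusted p = 0.000343 and 0.000225 (adjusted p = 0.0998 and 0.0913 with an estimated correlation). Interferon-stimulated genes moved differently in the 2 sets of controls. In approach 1, 12 of 26 fell (12 adjusted over the list alone), with a median of -0.21 and a camera adjusted p = 0.00654 (adjusted p = 0.454 with an estimated correlation). In approach 2, 23 of 26 rose and 2 fell (23 and 2 adjusted over the list alone), with a median of 0.96 and a camera adjusted p = 4.98e-11 (adjusted p = 0.0621 with an estimated correlation). The antiviral gene Rsad2 fell by 1.16 ± 0.14 in approach 1, and Ifit3 rose by 1.56 ± 0.13 in approach 2, a difference that was not tested between the approaches. In all, 5494 genes passed in approach 1 (2748 higher and 2746 lower) and 6374 in approach 2 (2839 higher and 3535 lower). Separate fits gave 7291 and 5076. On deposited values without normalization 57.6% of the called genes of approach 2 were higher, against 44.5% after it. The actin 3'/5' probe ratio, a sign of RNA quality, was 0.31 ± 0.02 and 0.29 ± 0.04 log2 units (SD) at 120 h and 24 h in approach 1, and 0.54 ± 0.12 and 0.29 ± 0.07 in approach 2. The Gapdh 3'/5' ratio was -0.18 ± 0.02 and -0.28 ± 0.03 in approach 1, and -0.46 ± 0.08 and -0.32 ± 0.04 in approach 2, so both ratios differed with time in approach 2 and that of Gapdh in approach 1.

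Cyp1a1, a monooxygenase that oxidises polycyclic aromatic hydrocarbons and is switched on by the aryl hydrocarbon receptor, answered to nearly every treatment. It was measured by 1 probe set. At 24 h its deposited intensity with 0.5 µM BaP was 1771 ± 51.8 against 31.6 ± 7.50 in the controls (mean ± SD, n = 3), a log2 change of 5.21 ± 0.15. It rose by 5.11 ± 0.15 with 2 µM MCA, 2.48 ± 0.15 with 50 µM DAT and 0.71 ± 0.15 with 25 µM AAF, with adjusted p = 9.9e-31, 2.42e-30, 5.65e-17 and 0.0276, the last lost in 5 of the 6 leave-outs of 1 array. At 120 h the rises were 6.47 ± 0.15 with 0.5 µM BaP, 5.55 ± 0.15 with 2 µM MCA, 3.91 ± 0.15 with 50 µM DAT and 2.01 ± 0.15 with 25 µM AAF. In approach 2 at 24 h they were 3.12 ± 0.15 with 10 µM AAF, 5.10 ± 0.15 with 1.5 µM BaP, 5.15 ± 0.15 with 700 µM DAT and 5.04 ± 0.15 with 20 µM MCA. At 120 h they were 3.82 ± 0.15 with 10 µM AAF, 5.45 ± 0.15 with 0.1 µM BaP and 7.35 ± 0.15 with 0.1 µM MCA. With 0.2 µM DAT the difference was 0.01 ± 0.15 (interval -0.29 to 0.31), which did not pass (adjusted p = 0.992). Control intensities were near the added 16 units in places, so these folds understate the change. Cyp1b1, a related enzyme, was already abundant in the controls. It rose by 1.73 ± 0.07 with 0.5 µM BaP and 1.79 ± 0.07 with 2 µM MCA at 24 h.

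**Figure D1:**
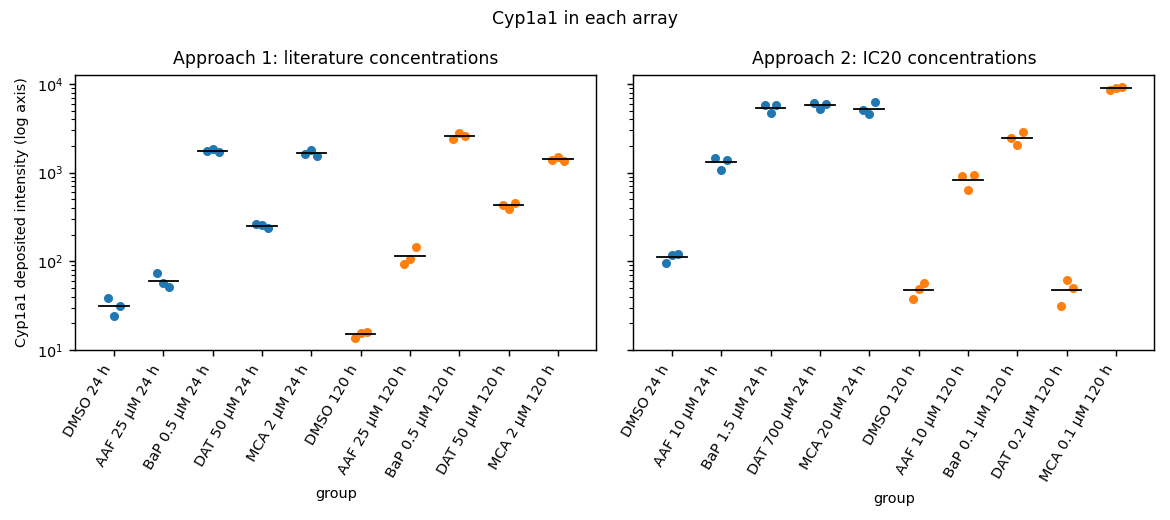
Deposited intensity of Cyp1a1 on a log axis for each of the 60 arrays, by group, with points for arrays (blue at 24 h, orange at 120 h) and a line at the mean of 3. The 3 arrays of 0.5 µM BaP at 24 h lay between 1733 and 1830 and their controls between 24.0 and 39.0.

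BaP at 0.5 µM for 24 h was compared with its controls to find the early response to a literature concentration. Genes of the aryl hydrocarbon receptor battery rose and interferon-stimulated genes fell. Of the receptor battery, 6 of 6 rose (6 adjusted over the list alone), with a median of 1.64 and a camera adjusted p = 2.17e-55. Next to Cyp1a1 these were Aldh3a1, an aldehyde dehydrogenase, at 2.11 ± 0.23, the quinone reductase Nqo1 at 1.55 ± 0.12 and Tiparp, a feedback inhibitor of the receptor, at 1.40 ± 0.07. In the interferon list, 19 of 26 fell (25 adjusted over the list alone), with a median of -0.74 and a camera adjusted p = 2.24e-63, led by the antiviral genes Mx2 at -1.53 ± 0.32, Ifit3 at -1.43 ± 0.13 and Rsad2 at -1.40 ± 0.14. In the oxidative stress list of Nrf2 targets, 10 of 21 rose (13 adjusted over the list alone), with a median of 0.35 and a camera adjusted p = 6.13e-19, with the glutathione synthesis enzyme Gclc at 0.59 ± 0.11. Genes of sterol synthesis fell, such as Hmgcs1 at -0.65 ± 0.13, and in that list 6 of 20 fell (11 adjusted over the list alone), with a median of -0.40 and a camera adjusted p = 1.11e-11. In the hypoxia and glycolysis list, 9 of 25 fell (11 adjusted over the list alone), with a median of -0.16 and a camera adjusted p = 6.21e-12, with Pfkl, a phosphofructokinase, at -0.999 ± 0.15. Of the extracellular matrix list, 7 of 29 fell (7 adjusted over the list alone), with a median of -0.16 and a camera adjusted p = 7.92e-07 (adjusted p = 0.103 with an estimated correlation), with fibromodulin (Fmod) at -1.40 ± 0.22. Of the p53 targets, 3 of 27 rose (4 adjusted over the list alone), with a median of 0.12 and a camera adjusted p = 8.14e-05, while Cdkn1a, the cell-cycle inhibitor p21, was at 0.27 ± 0.18 and did not pass (adjusted p = 0.741), but passed with the replicate number as a block (adjusted p = 0.00241). For the genes that passed the highest adjusted p was 0.0016. The Gapdh 3'/5' ratio was lower in all 3 pairs of arrays (-0.31 ± 0.02 against -0.28 ± 0.03). In all, 374 genes passed (147 higher and 227 lower, 41 of them by at least 2-fold). Taking the replicate number as a block gave 1181 genes and a separate fit of approach 1 gave 1190. The count was 249 without BaP replicate 1 and 249 without control replicate 3.

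BaP at 1.5 µM for 24 h, the IC20 concentration, was compared with the controls of approach 2. Receptor battery and oxidative stress genes rose, and sterol synthesis genes fell. In the receptor battery, 6 of 6 rose (6 adjusted over the list alone), with a median of 1.54 and a camera adjusted p = 4.88e-34, with Nqo1 at 1.85 ± 0.12 and Tiparp at 1.64 ± 0.07. In the cholesterol synthesis list, 15 of 20 fell (19 adjusted over the list alone), with a median of -0.71 and a camera adjusted p = 9.22e-24, such as Nsdhl at -0.94 ± 0.10 and Mvd at -0.92 ± 0.16. In the Nrf2 list, 11 of 21 rose (13 adjusted over the list alone), with a median of 0.30 and a camera adjusted p = 5.9e-13, with Gstm1, a glutathione transferase, at 0.66 ± 0.07. Of the p53 targets, 6 of 27 rose (11 adjusted over the list alone), with a median of 0.27 and a camera adjusted p = 2.06e-07, and Cdkn1a rose by 1.01 ± 0.18 and the growth-arrest gene Gadd45a by 1.04 ± 0.14. In the interferon list, 1 of 26 rose and 13 fell (4 and 18 adjusted over the list alone), with a median of -0.41 and a camera adjusted p = 1.81e-12 (adjusted p = 0.063 with an estimated correlation), with Mx2 at -1.93 ± 0.32. Of genes linked to the integrated stress response and the endoplasmic reticulum, 8 of 26 rose (12 adjusted over the list alone), with a median of 0.19 and a camera adjusted p = 4.04e-07. The heme synthesis enzyme Cpox rose by 1.72 ± 0.24 and the prostaglandin synthase Ptgs2 by 1.44 ± 0.19. The highest adjusted p among these genes was 0.000114. Actin 3'/5' ratios were higher in all 3 pairs of arrays (0.40 ± 0.08 against 0.29 ± 0.07). In all, 821 genes passed (417 higher and 404 lower, a share of 50.8% higher, or 65.1% on deposited values). As a block, the replicate number gave 2360 genes. A separate fit of approach 2 called 303 and a fit of the 6 arrays alone 78. The count was 512 without control replicate 2.

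MCA was given at 2 µM for 24 h in approach 1. The receptor battery rose and interferon genes fell. Of the receptor battery, 6 of 6 rose (6 adjusted over the list alone), with a median of 1.43 and a camera adjusted p = 7.83e-93, with Aldh3a1 at 1.61 ± 0.23, Tiparp at 1.25 ± 0.07 and Nqo1 at 0.94 ± 0.12. In the interferon list, 9 of 26 fell (20 adjusted over the list alone), with a median of -0.40 and a camera adjusted p = 7.39e-48, such as Rsad2 at -0.90 ± 0.14 and Ifit3 at -0.89 ± 0.13. In the inflammatory list, 3 of 22 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.13 and a camera adjusted p = 4.54e-05, with Ptgs2 at 1.06 ± 0.19 and the chemokine Ccl5 at -0.86 ± 0.12. The chitinase-like gene Chil1 rose by 1.53 ± 0.24. Of the p53 targets, 1 of 27 rose (1 adjusted over the list alone), with a median of 0.04 and a camera adjusted p = 0.00813 (adjusted p = 0.0594 with an estimated correlation). The member that passed was the early response gene Ier3 at 1.29 ± 0.12, and Cdkn1a was at -0.13 ± 0.18 and did not pass. Among the genes that passed the highest adjusted p was 0.000528. In all, 89 genes passed (45 higher and 44 lower), and 281 in a separate fit of approach 1. The count was 57 without control replicate 2, 52 without control replicate 3 and 54 without MCA replicate 1.

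At 20 µM for 24 h in approach 2, MCA lowered sterol synthesis genes. In the cholesterol synthesis list, 17 of 20 fell (18 adjusted over the list alone), with a median of -0.68 and a camera adjusted p = 8.14e-29, such as Msmo1 at -0.99 ± 0.16 and Idi1 at -1.09 ± 0.18. In the receptor battery, 5 of 6 rose (6 adjusted over the list alone), with a median of 1.22 and a camera adjusted p = 1.11e-33, with Tiparp at 1.69 ± 0.07 and Nqo1 at 1.13 ± 0.12. Of the p53 targets, 7 of 27 rose (7 adjusted over the list alone), with a median of 0.16 and a camera adjusted p = 3.67e-05, with Ier3 at 1.22 ± 0.12 and Cdkn1a at 0.69 ± 0.18, whose call was lost in a separate fit (adjusted p = 0.155) and without MCA replicate 1 or control replicates 2 or 3 (adjusted p up to 0.15). In the interferon list, 1 of 26 rose and 9 fell (2 and 14 adjusted over the list alone), with a median of -0.32 and a camera adjusted p = 1.08e-08 (adjusted p = 0.152 with an estimated correlation), with Ifit1 at -0.95 ± 0.14. The growth factor Igf1 fell by 1.34 ± 0.26 and Ptgs2 rose by 1.28 ± 0.19. For these genes the highest adjusted p was 0.0115. In all 3 pairs of arrays the actin 3'/5' ratio was higher (0.42 ± 0.11 against 0.29 ± 0.07). In all, 588 genes passed (275 higher and 313 lower, a share of 46.8% higher, or 58% on deposited values). The replicate number as a block gave 1994 genes. A separate fit of approach 2 called 166 and a fit of the 6 arrays alone 40. The count was 368 without control replicate 2.

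The 2 hydrocarbons were then compared with each other at 24 h, at the concentrations used, which differ. Induction of Cyp1a1 was not shown to differ, with BaP minus MCA at 0.10 ± 0.15 (interval -0.20 to 0.41) for 0.5 µM against 2 µM and 0.07 ± 0.15 (interval -0.23 to 0.37) for 1.5 µM against 20 µM. Nqo1 was higher with BaP in both, by 0.61 ± 0.12 (interval 0.36 to 0.85) and 0.72 ± 0.12 (interval 0.48 to 0.97), though the first call was lost without MCA replicate 3 (adjusted p = 0.0565). In approach 1 the matrix genes thrombospondin 1 (Thbs1) at -0.99 ± 0.14 and Tnc at -0.89 ± 0.14 and the phosphofructokinase Pfkl at -0.88 ± 0.15 were lower with BaP. The highest adjusted p among those genes was 0.00457 in approach 1, and that of Nqo1 in approach 2 was 0.000865. The first comparison called 89 genes (42 higher with BaP and 47 lower), 387 in a separate fit of approach 1. It called 44, 47 and 41 without BaP replicates 1, 2 and 3, and 46 and 49 without MCA replicates 1 and 2. The second called 69 (38 and 31). The replicate block gave 300 genes, a separate fit 10 and leaving out BaP replicate 1 gave 34. Of the genes each called against the shared controls, 32 were higher and 41 lower with both 0.5 µM BaP and 2 µM MCA, where independent lists would share 0.5 and 0.8. With 1.5 µM BaP and 20 µM MCA 173 were higher and 183 lower with both, where independent lists would share 9.1 and 10 and simulated unchanged groups shared 2.65 on average. Across genes, which are not independent replicates, log2 changes with 0.5 µM BaP and 2 µM MCA correlated at 0.697 with a covariance of 0.0200, against 0.497 and 0.00657 in 20 simulations of unchanged groups. The values for 1.5 µM BaP and 20 µM MCA were 0.671 and 0.0537 against 0.501 and 0.0300. The 3 controls were too few to split, so part of each excess may come from sharing them.

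DAT at 50 µM for 24 h changed few genes. Cyp1a1 rose by 2.48 ± 0.15 and Cyp1b1 by 0.98 ± 0.07, and Nrp2, a co-receptor of semaphorins, fell by 0.52 ± 0.10 (highest adjusted p = 0.0185). Nrp2 lost its call without DAT replicates 2 or 3 or control replicates 1 or 2 (adjusted p up to 0.619). Of the receptor battery, 2 of 6 rose (6 adjusted over the list alone), with a median of 0.59 and a camera adjusted p = 1.25e-39. Of the DNA replication list, 0 of 30 passed over all genes (3 rose and 0 fell adjusted over the list alone), with a median of 0.17 and a camera adjusted p = 1.91e-11 (adjusted p = 0.0525 with an estimated correlation). These 3 genes were the ones that passed, with 400 at an unadjusted p under 0.05. With the replicate number as a block 86 genes passed, in a separate fit of approach 1 22, without the 3 arrays that stand apart 8, and 6 without control replicate 3. Gapdh 3'/5' ratios were lower in all 3 pairs of arrays (-0.30 ± 0.03 against -0.28 ± 0.03).

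At 700 µM, the IC20 concentration for 24 h, DAT moved stress and inflammatory genes. Of the p53 targets, 13 of 27 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.44 and a camera adjusted p = 2.88e-10, led by Gadd45a at 2.13 ± 0.14, Ier3 at 1.54 ± 0.12 and Cdkn1a at 1.35 ± 0.18. In the inflammatory list, 13 of 22 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.64 and a camera adjusted p = 2.93e-09, with the chemokine Ccl20 at 2.25 ± 0.27 and Ptgs2 at 1.75 ± 0.19. In the stress response list, 14 of 26 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.38 and a camera adjusted p = 3.27e-09, with Dnajb9, a chaperone of the endoplasmic reticulum, at 1.18 ± 0.14, the pro-apoptotic factor Ddit3 at 0.93 ± 0.08 and Chac1 at 1.01 ± 0.14. In the receptor battery, 5 of 6 rose (6 adjusted over the list alone), with a median of 1.30 and a camera adjusted p = 1.37e-20, with Cyp1b1 at 1.79 ± 0.07 and Tiparp at 1.51 ± 0.07. In the cholesterol synthesis list, 11 of 20 fell (13 adjusted over the list alone), with a median of -0.71 and a camera adjusted p = 6.97e-12, with Fdps at -1.17 ± 0.27 and Sqle at -0.94 ± 0.11. Of the interferon list, 13 of 26 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.24 and a camera adjusted p = 7.01e-05 (adjusted p = 0.351 with an estimated correlation), with Rsad2 at 1.28 ± 0.14. The largest falls were in genes known from the early mouse embryo, Tcstv1 at -3.17 ± 0.22 and Zfp352 at -2.08 ± 0.20. Among these genes the highest adjusted p was 0.0016. With DAT the actin 3'/5' ratio was higher in all 3 pairs of arrays (0.38 ± 0.08 against 0.29 ± 0.07) and that of Gapdh lower (-0.35 ± 0.04 against -0.32 ± 0.04). In all, 2105 genes passed (1085 higher and 1020 lower). As a block, the replicate number gave 4109 genes, a separate fit of approach 2 gave 992 and a fit of the 6 arrays alone 562.

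AAF changed few genes at 24 h. At 25 µM for 24 h Cyp1a1 rose by 0.71 ± 0.15 and Cyp1b1 by 0.61 ± 0.07, and the matrix Gla protein gene Mgp by 0.65 ± 0.14, while the phosphate transporter Slc20a1 fell by 0.51 ± 0.10 (highest adjusted p = 0.0323). Of these 4, Cyp1b1 kept its call whichever array was left out. The others each lost it without AAF replicates 1 or 3 or control replicate 2, among others, with adjusted p up to 0.488 for Cyp1a1, 0.347 for Mgp and 0.31 for Slc20a1. Of the extracellular matrix list, 1 of 29 rose (10 adjusted over the list alone), with a median of 0.23 and a camera adjusted p = 5.83e-21. Control replicate 3 stood apart, with deposited Postn of 224.6 and Fmod of 305.6. The other controls had 105.3 and 106.6, and 180.7 and 167.8, and the AAF arrays 227.2 to 289.2, and 280.9 to 384. Control replicate 3 and all AAF arrays shared low Pde6b, which parts arrays in approach 1, so the matrix rise may follow that split. Of the receptor battery, 2 of 6 rose (3 adjusted over the list alone), with a median of 0.41 and a camera adjusted p = 5.05e-11. With AAF the Gapdh 3'/5' ratio was lower in all 3 pairs of arrays (-0.31 ± 0.01 against -0.28 ± 0.03). In all, 12 genes passed (8 higher and 4 lower). The replicate number as a block gave 258 genes, a separate fit of approach 1 gave 115 and deposited values 1. Leaving out arrays gave 2 without AAF replicate 1, 1 without AAF replicate 3, 3 without control replicate 1 and 2 without control replicate 2. A fit of the 6 arrays alone called 0, where Cyp1a1 had an adjusted p of 0.138, and 568 genes had an unadjusted p under 0.05 in the shared fit.

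AAF at 10 µM for 24 h, in approach 2, raised Cyp1a1 by 3.12 ± 0.15, Cyp1b1 by 0.89 ± 0.07 and Nqo1 by 0.55 ± 0.12 (highest adjusted p = 0.0361). Nqo1 lost its call whichever of the 6 arrays was left out (adjusted p up to 0.13). In the receptor battery, 5 of 6 rose (5 adjusted over the list alone), with a median of 0.53 and a camera adjusted p = 1.18e-34. In the cholesterol synthesis list, 0 of 20 passed over all genes or adjusted over the list alone, with a median of -0.23 and a camera adjusted p = 8.92e-10. Of the 3 pairs of arrays all had a higher actin 3'/5' ratio with AAF (0.37 ± 0.03 against 0.29 ± 0.07). In all, 22 genes passed (13 higher and 9 lower, a share of 59.1% higher, or 85.7% of 14 on deposited values). Taking the replicate number as a block gave 67 genes. A separate fit of approach 2 called 3 and a fit of the 6 arrays alone 3. The count was 11 without AAF replicate 2 and 14 without control replicate 1.

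**Figure D2:**
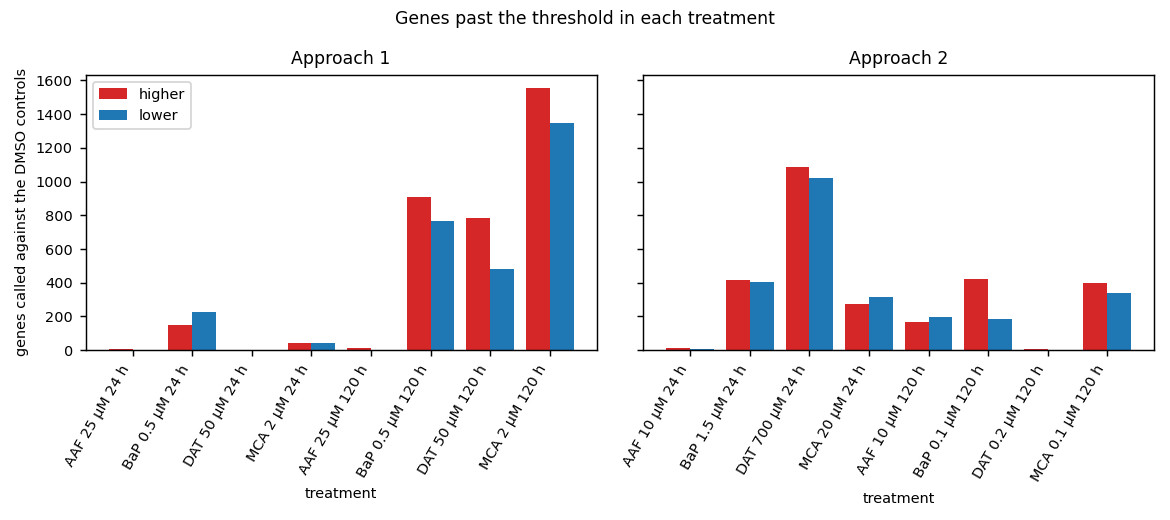
Number of genes past the threshold in each treatment against the DMSO controls of its approach and time, as bars from 0 for genes that were higher (red) and lower (blue). The highest bars are those of 2 µM MCA at 120 h, with 1557 higher and 1349 lower.

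After 120 h with 0.5 µM BaP, cell division genes stood above the controls of the same time and matrix genes below them. In the mitosis list, 29 of 29 rose (29 adjusted over the list alone), with a median of 0.86 and a camera adjusted p = 1.07e-43, with the topoisomerase Top2a at 1.51 ± 0.06 and Cenpf at 1.21 ± 0.14. In the DNA replication list, 20 of 30 rose (23 adjusted over the list alone), with a median of 0.57 and a camera adjusted p = 4.78e-22, with cyclin E1 (Ccne1) at 1.35 ± 0.12. In the extracellular matrix list, 2 of 29 rose and 15 fell (3 and 17 adjusted over the list alone), with a median of -0.40 and a camera adjusted p = 6.59e-11, with Postn at -2.95 ± 0.20 and Fmod at -2.49 ± 0.22. Agt, which had risen with time in the controls, was -2.71 ± 0.38. In the inflammatory list, 10 of 22 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.17 and a camera adjusted p = 0.000208, with Ptgs2 at 2.53 ± 0.19 and the acute-phase gene Saa3 at 1.90 ± 0.24. Of the Nrf2 targets, 13 of 21 rose (15 adjusted over the list alone), with a median of 0.33 and a camera adjusted p = 9.57e-11, and of the stress response list, 13 of 26 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.27 and a camera adjusted p = 4.2e-07, with Gclc at 1.16 ± 0.11 and Trib3 at 0.91 ± 0.11. In the DNA repair list, 8 of 29 rose (9 adjusted over the list alone), with a median of 0.17 and a camera adjusted p = 0.000106, with Brca1 at 1.24 ± 0.09. In the smooth muscle list, 3 of 9 fell (4 adjusted over the list alone), with a median of -0.15 and a camera adjusted p = 2.19e-05. Of the p53 targets, 6 of 27 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.23 and a camera adjusted p = 0.00192, with Ier3 at 1.25 ± 0.12 and Sesn1 at -0.59 ± 0.10. For these genes the highest adjusted p was 2.37e-05. The actin 3'/5' ratios of the 3 BaP arrays all lay above those of the controls (0.44 ± 0.06 against 0.31 ± 0.02). In all, 1672 genes passed (906 higher and 766 lower, 171 of them by at least 2-fold). As a block, the replicate number gave 3191 genes and a separate fit of approach 1 gave 3384.

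MCA at 2 µM for 120 h gave the highest count of the treatments. In the mitosis list, 29 of 29 rose (29 adjusted over the list alone), with a median of 1.26 and a camera adjusted p = 1.98e-48, with cyclin B2 (Ccnb2) at 1.70 ± 0.14. In the DNA replication list, 26 of 30 rose (27 adjusted over the list alone), with a median of 1.15 and a camera adjusted p = 1.42e-34, with the thymidine kinase Tk1 at 1.93 ± 0.16 and the ribonucleotide reductase subunit Rrm2 at 1.91 ± 0.15. The matrix protease stromelysin (Mmp3) rose by 4.60 ± 0.30, the collagenase Mmp13 by 2.32 ± 0.22, the transcription factor Fosl1 by 3.33 ± 0.25, the membrane protein Dynap by 3.78 ± 0.34 and the semaphorin Sema5a by 3.11 ± 0.30. In the smooth muscle list, 6 of 9 fell (6 adjusted over the list alone), with a median of -0.65 and a camera adjusted p = 1.24e-06, with the contractile genes Actg2 at -2.25 ± 0.16, Myl9 at -2.16 ± 0.18 and Acta2 at -2.05 ± 0.09. In the extracellular matrix list, 17 of 29 fell (21 adjusted over the list alone), with a median of -0.46 and a camera adjusted p = 6.59e-11, with Postn at -1.92 ± 0.20. Of the immediate early genes, 12 of 27 rose and 6 fell (12 and 6 adjusted over the list alone), with a median of 0.26 and a camera adjusted p = 0.0129 (adjusted p = 0.431 with an estimated correlation) and 0.0633 in a separate fit, with Ereg, a ligand of the epidermal growth factor receptor, at 2.38 ± 0.16. The highest adjusted p among these genes was 5.82e-11. Pde6b, a phosphodiesterase subunit of photoreceptors, was the largest fall at -2.52 ± 0.48, but its deposited intensity in the 3 controls was 6, 228.7 and 185.8. With MCA the Gapdh 3'/5' ratio was lower in all 3 pairs of arrays (-0.19 ± 0.01 against -0.18 ± 0.02). In all, 2906 genes passed (1557 higher and 1349 lower, 315 of them by at least 2-fold). The replicate number as a block gave 4668 genes and a separate fit of approach 1 gave 4947.

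The direct comparison of 0.5 µM BaP with 2 µM MCA at 120 h called 3129 genes (1559 higher with BaP and 1570 lower). The replicate block gave 4945 and a separate fit 5264. Pde6b, which also parts control arrays, was high in all BaP and low in all MCA arrays, so the count may hold that split. Sema5a at -4.83 ± 0.30, Mmp3 at -4.54 ± 0.30, Mmp13 at -3.56 ± 0.22 and Dynap at -3.52 ± 0.34 were lower with BaP. The chemokine Cxcl1 was higher by 1.41 ± 0.15 and the surface marker Thy1 by 1.55 ± 0.15. Cyp1a1 was higher with BaP by 0.91 ± 0.15 (interval 0.61 to 1.21) and Nqo1 lower, at -1.02 ± 0.12 (interval -1.27 to -0.77). Among these genes the highest adjusted p was 5.7e-06. Against the shared controls, both compounds raised 462 genes and lowered 333, and moved 111 in opposite directions, where independent lists would give 111.6, 81.8 and 191.1. Their log2 changes correlated at 0.470 across genes with a covariance of 0.0540, against 0.500 and 0.00663 in 20 simulations of unchanged groups. All 3 BaP arrays lay above the MCA arrays in the actin 3'/5' ratio (0.44 ± 0.06 against 0.30 ± 0.03) and in that of Gapdh (-0.12 ± 0.04 against -0.19 ± 0.01).

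DAT at 50 µM for 120 h moved many of the genes that MCA moved. In the mitosis list, 29 of 29 rose (29 adjusted over the list alone), with a median of 0.93 and a camera adjusted p = 1.53e-59, with Ccnb2 at 1.28 ± 0.14. In the DNA replication list, 25 of 30 rose (26 adjusted over the list alone), with a median of 0.78 and a camera adjusted p = 2.92e-37, with Tk1 at 1.37 ± 0.16. Mmp3 rose by 3.79 ± 0.30, Dynap by 2.69 ± 0.34, Sema5a by 2.60 ± 0.30 and Fosl1 by 2.33 ± 0.25. In the smooth muscle list, 6 of 9 fell (6 adjusted over the list alone), with a median of -0.45 and a camera adjusted p = 2.85e-06, with Actg2 at -1.84 ± 0.16 and Myl9 at -1.06 ± 0.18. In the interferon list, 20 of 26 rose (23 adjusted over the list alone), with a median of 0.48 and a camera adjusted p = 3.04e-22, with Rsad2 at 1.04 ± 0.14 and the transcription factor Irf7 at 0.86 ± 0.14. Of the receptor battery, 6 of 6 rose (6 adjusted over the list alone), with a median of 1.17 and a camera adjusted p = 5.63e-20, with Aldh3a1 at 1.92 ± 0.23. Of the extracellular matrix list, 1 of 29 rose and 5 fell (2 and 11 adjusted over the list alone), with a median of -0.21 and a camera adjusted p = 0.000192 (adjusted p = 0.24 with an estimated correlation), with lumican (Lum) rising by 1.46 ± 0.27. For these genes the highest adjusted p was 8.36e-05. In all, 1269 genes passed (785 higher and 484 lower, 107 of them by at least 2-fold) and 3001 in a separate fit of approach 1. DAT and MCA raised 710 genes together and lowered 454, with 10 in opposite directions, where independent lists would give 96.7, 51.7 and 143.4. Their log2 changes correlated at 0.883 across genes with a covariance of 0.0889, against 0.498 and 0.00654 in 20 simulations of unchanged groups. The shared controls, and low Pde6b in all arrays of both groups, may add to the excess.

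With 25 µM AAF for 120 h Cyp1a1 rose by 2.01 ± 0.15, Mmp3 by 1.88 ± 0.30, Cyp1b1 by 0.89 ± 0.07 and the stem cell factor Kitl by 0.82 ± 0.17 (highest adjusted p = 0.0167). Mmp3 lost its call without AAF replicate 3 (adjusted p = 0.119), and Kitl without AAF replicates 2 or 3 or control replicates 2 or 3 (adjusted p up to 1). In the receptor battery, 2 of 6 rose (5 adjusted over the list alone), with a median of 0.53 and a camera adjusted p = 5.03e-41. For the mitosis list, 0 of 29 passed over all genes or adjusted over the list alone, with a median of 0.15 and a camera adjusted p = 1.25e-13 (adjusted p = 0.0712 with an estimated correlation). All 3 AAF arrays lay above the controls in the actin 3'/5' ratio (0.37 ± 0.03 against 0.31 ± 0.02), and the Gapdh ratio was higher in all 3 pairs (-0.13 ± 0.04 against -0.18 ± 0.02). In all, 12 genes passed (11 higher and 1 lower). As a block, the replicate number gave 62 genes and a separate fit of approach 1 gave 45, with 3 in a fit of the 6 arrays alone. The count was 39, 6 and 2 without AAF replicates 1, 2 and 3, and 3 and 4 without control replicates 2 and 3.

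In approach 2 the 120 h concentrations of BaP and MCA were both 0.1 µM. Interferon-stimulated genes fell with both. With MCA, 16 of 26 fell (19 adjusted over the list alone), with a median of -0.57 and a camera adjusted p = 3.61e-31, with Rsad2 at -1.90 ± 0.14, Mx2 at -1.71 ± 0.32 and Ifit1 at -1.39 ± 0.14. With BaP, 12 of 26 fell (17 adjusted over the list alone), with a median of -0.33 and a camera adjusted p = 6.56e-15, with Rsad2 at -0.83 ± 0.14 and Oas1a at -0.73 ± 0.11. Of the receptor battery, 6 of 6 rose (6 adjusted over the list alone), with a median of 1.44 and a camera adjusted p = 5.59e-36 with MCA, and 5 of 6 rose (6 adjusted over the list alone), with a median of 0.65 and a camera adjusted p = 1.41e-21 with BaP. Ptgs2 rose by 2.30 ± 0.19 with MCA and 1.30 ± 0.19 with BaP, Chil1 by 2.28 ± 0.24 and 1.92 ± 0.24, and the transcription factor Klf2 by 1.20 ± 0.15 and 0.97 ± 0.15. In the mitosis list, 12 of 29 fell (15 adjusted over the list alone), with a median of -0.32 and a camera adjusted p = 7.54e-12 (adjusted p = 0.102 with an estimated correlation) with MCA, and 5 of 29 fell (8 adjusted over the list alone), with a median of -0.19 and a camera adjusted p = 4.08e-09 (adjusted p = 0.167 with an estimated correlation) with BaP. Cdc20, which drives exit from mitosis, was -0.90 ± 0.13 with MCA and -0.76 ± 0.13 with BaP. The matrix gene Postn, at -1.67 ± 0.20 with MCA and -1.04 ± 0.20 with BaP, and the lipid carrier Apod, at -1.89 ± 0.22 and -1.38 ± 0.22, fell with both. The highest adjusted p among these genes was 0.000216 with MCA and 0.000343 with BaP. MCA changed 734 genes (396 higher and 338 lower). The replicate number as a block gave 2217 genes, a separate fit of approach 2 gave 312 and a fit of the 6 arrays alone 101. BaP changed 604 (420 and 184), 182 in a separate fit, 23 in a fit of the 6 arrays alone, 343 on deposited values, and 351 without BaP replicate 1 and 383 without control replicate 2. The Gapdh 3'/5' ratio with MCA was higher in all 3 pairs of arrays (-0.36 ± 0.13 against -0.46 ± 0.08).

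At this matched dose and time the direct test found weaker induction of Cyp1a1 by BaP, at -1.90 ± 0.15 (interval -2.20 to -1.60) relative to MCA, and of Tiparp, at -0.91 ± 0.07 (interval -1.05 to -0.76). Ptgs2 was lower with BaP, at -1.003 ± 0.19, a call lost in a separate fit (adjusted p = 0.181) and without MCA replicate 1 (adjusted p = 0.0545), and Rsad2 higher, by 1.07 ± 0.14 (highest adjusted p = 0.00288). Nqo1 was at -0.39 ± 0.12 (interval -0.64 to -0.14), which did not pass (adjusted p = 0.216) but passed with the replicate number as a block (adjusted p = 0.0251). Between the compounds the actin 3'/5' ratio was lower with BaP in all 3 pairs (0.54 ± 0.18 against 0.58 ± 0.18). In all, 54 genes passed (34 higher with BaP and 20 lower). The replicate block gave 282 genes, a separate fit 10, deposited values 32 and leaving out BaP replicate 1 gave 34. Against the shared controls 238 genes were higher and 119 lower with both, where independent lists would share 13.2 and 4.9 and simulated unchanged groups shared 2.5 on average. The log2 changes correlated at 0.729 across genes with a covariance of 0.0572, against 0.500 and 0.0296 in the simulations. Wrong groupings with these controls called up to 442 (BaP) and 1475 (MCA) genes, so shared controls may give more than 2.5 without an effect.

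AAF at 10 µM for 120 h lowered genes of cell division. In the mitosis list, 15 of 29 fell (25 adjusted over the list alone), with a median of -0.40 and a camera adjusted p = 3.99e-26, and in the DNA replication list, 10 of 30 fell (19 adjusted over the list alone), with a median of -0.33 and a camera adjusted p = 2e-15, with Ndc80, a kinetochore gene, at -0.64 ± 0.14 and the replication gene Mcm5 at -0.59 ± 0.14. Both lost their call without AAF replicate 1 or control replicate 3 (adjusted p up to 0.107 and 0.149), and Ndc80 in a separate fit (adjusted p = 0.125). In the interferon list, 6 of 26 fell (19 adjusted over the list alone), with a median of -0.33 and a camera adjusted p = 2.12e-16, with Rsad2 at -1.04 ± 0.14. Cyp1a1 rose by 3.82 ± 0.15, Ptgs2 by 1.09 ± 0.19 and Cyp1b1 by 0.95 ± 0.07, and in the receptor battery, 3 of 6 rose (4 adjusted over the list alone), with a median of 0.28 and a camera adjusted p = 9.88e-13. Among these genes the highest adjusted p was 0.0114. In all 3 pairs the Gapdh 3'/5' ratio was higher with AAF (-0.38 ± 0.08 against -0.46 ± 0.08). In all, 367 genes passed (168 higher and 199 lower, a share of 45.8% higher, or 32.5% of 157 on deposited values). As a block, the replicate number gave 2066 genes. A separate fit of approach 2 called 71 and a fit of the 6 arrays alone 2. The count was 138 without AAF replicate 1, 232 without control replicate 2 and 151 without control replicate 3.

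DAT at 0.2 µM for 120 h was the treatment with the fewest receptor genes. Of the battery, 0 of 6 passed over all genes or adjusted over the list alone, with a median of -0.03 and a camera adjusted p = 0.419. The kinase gene Brsk1 rose by 1.53 ± 0.27 and the serine protease Prss21 fell by 1.47 ± 0.29 (highest adjusted p = 0.0172). The 8 genes that passed fell to 0 in a separate fit of approach 2, in a fit of the 6 arrays alone and without DAT replicate 2, and 1419 had an unadjusted p under 0.05 in the shared fit. Leaving out control replicates 1 and 2 gave 21 and 5, and DAT replicates 1, 2 and 3 gave 3, 0 and 22. Deposited values gave 1 gene, which was lower (0% higher, against 87.5%). Brsk1 lost its call without DAT replicate 2 (adjusted p = 0.0814) and Prss21 without DAT replicates 1 or 2 or control replicates 1 or 3 (adjusted p up to 0.0849).

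**Figure D3:**
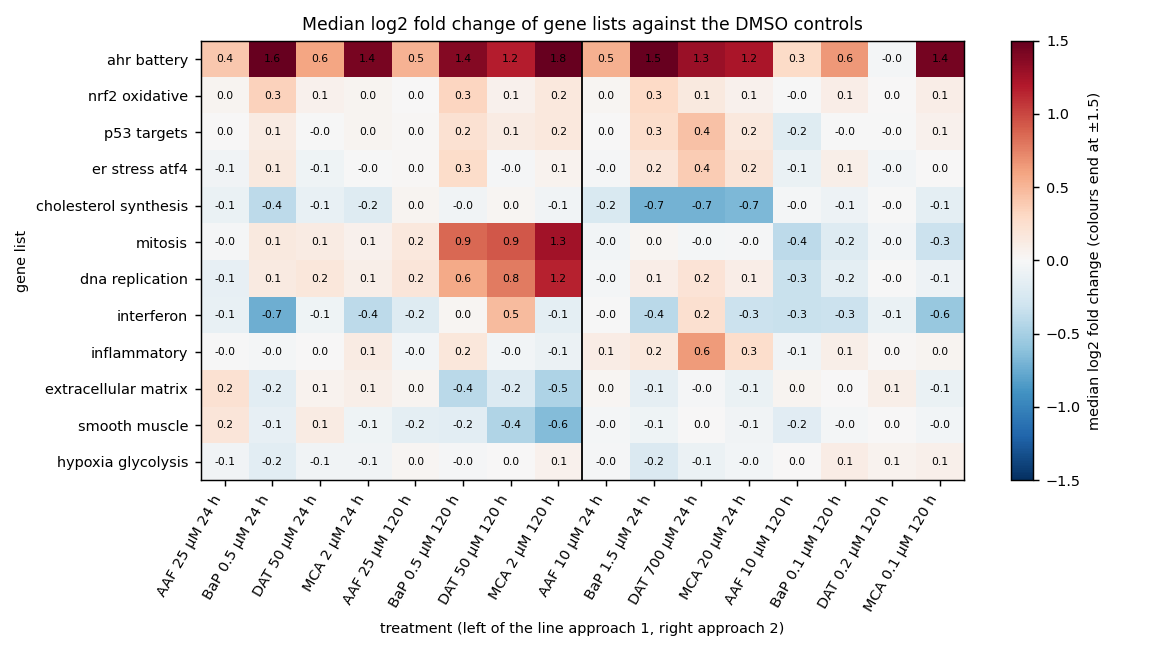
Median log2 change of 12 gene lists (vertical axis) in the 16 treatments (horizontal axis) against the DMSO controls of the same approach and time, with red for higher and blue for lower. The mitosis list reached 1.26 with 2 µM MCA at 120 h and -0.40 with 10 µM AAF at 120 h.

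Whether a response changed with time was tested where the concentration was the same at 24 h and 120 h, as the 120 h response minus the 24 h response. For 2 µM MCA 1550 genes differed (945 more positive at 120 h and 605 more negative). The replicate number as a block gave 3010 genes, a separate fit of approach 1 gave 3560 and leaving out the 3 arrays that stand apart gave 732. Mmp3 differed by 4.71 ± 0.42, Dynap by 3.88 ± 0.48 and Sema5a by 3.41 ± 0.43, and the contractile genes Actg2 by -2.10 ± 0.22 and Myl9 by -1.85 ± 0.26. Cyp1a1 was not shown to differ, at 0.45 ± 0.21 (interval 0.02 to 0.87). For 50 µM DAT 331 genes differed (276 and 55), 807 with the block, 1037 in a separate fit, 208 on deposited values, 184 without the 3 arrays that stand apart and 199 without control replicate 1 at 120 h. Mmp3 differed by 3.41 ± 0.42, Sema5a by 2.37 ± 0.43 and Actg2 by -1.90 ± 0.22. For 0.5 µM BaP 366 genes differed (248 and 118), 869 with the block, 1075 in a separate fit, 190 without the 3 arrays that stand apart and 216 without control replicate 1 at 120 h. Rsad2 differed by 2.15 ± 0.20, Agt by -2.72 ± 0.53 and Cyp1a1 by 1.25 ± 0.21. For 25 µM AAF Cyp1a1 was the 1 gene that differed, by 1.30 ± 0.21. With the block 7 genes differed, in a separate fit 7 and in a fit of these groups alone 0. There were 2 without AAF replicate 2 at 24 h, 13 without AAF replicate 1 at 120 h and 2 without control replicate 3 at 24 h. In the controls Cyp1a1 changed by -0.64 ± 0.15 from 24 h to 120 h, which is part of the 1.30 and of the 1.25 with BaP. For 10 µM AAF 5 genes differed, 179 with the block and 0 in a separate fit of approach 2. An unadjusted p under 0.05 was found for 1073. Leaving out AAF replicates 1, 2 and 3 of 24 h gave 13, 1 and 10, and those of 120 h gave 2, 15 and 30. Leaving out control replicates 1, 2 and 3 of 24 h gave 3, 9 and 1. Leaving out control replicates 1 and 3 of 120 h gave 34 and 2.

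Between the approaches the concentrations of each compound differed, and so did the processing of the deposited values, so responses were set side by side and their difference was not tested. At 24 h, 0.5 µM and 1.5 µM BaP raised 113 genes in both approaches and lowered 138, with 1 in opposite directions, where independent lists would give 4.9, 7.3 and 12.2. For 2 µM and 20 µM MCA at 24 h, 29 genes were higher and 31 lower in both, with 1 opposite, against 1, 1.1 and 2.1. At 120 h, 0.5 µM and 0.1 µM BaP shared 216 genes with the same direction, 63 of them lower, with 27 opposite, against 41.3, 11.2 and 38.7. For 2 µM and 0.1 µM MCA at 120 h, 113 were higher and 121 lower in both and 120 opposite, against 48.8, 36.1 and 83.9. The mitosis list had a median of 0.86 with 0.5 µM BaP, 1.26 with 2 µM MCA and 0.93 with 50 µM DAT at 120 h in approach 1, and of -0.19 with 0.1 µM BaP, -0.32 with 0.1 µM MCA and -0.40 with 10 µM AAF at 120 h in approach 2.

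The lists of adipocyte (8 measured members), endothelial (3), epithelial (5) and macrophage (8) markers were called in 0 of the 16 treatments by camera, with list medians between -0.21 and 0.12, -0.31 and 0.15, -0.40 and 0.38, and -0.17 and 0.17. Without the filter the epithelial list was called with 700 µM DAT (adjusted p = 0.0371). The growth arrest list (22 members) was also called in 0 of 16 (medians -0.18 to 0.12), though with 0.1 µM BaP it was on deposited values (adjusted p = 0.0224), without the filter (adjusted p = 0.0261) and with the replicate number as a block (adjusted p = 0.0391), and it rose over time in the controls, with 12 members rising and 4 falling in approach 1 (adjusted p = 0.0175, and 0.0252 with an estimated correlation). In approach 2 13 rose and 4 fell (adjusted p = 0.0459), a call lost with an estimated correlation (adjusted p = 0.0521) and on deposited values (adjusted p = 0.275). The heat shock list (17) rose in 1 treatment, 0.5 µM BaP at 120 h, where 4 of 17 rose (4 adjusted over the list alone), with a median of 0.10 and a camera adjusted p = 0.0263 (adjusted p = 0.109 with an estimated correlation), and was not called there on deposited values (adjusted p = 0.0961). With 2 µM MCA at 120 h it was not called (adjusted p = 0.0903), but rose with the replicate number as a block (adjusted p = 0.0358), in a separate fit (adjusted p = 0.0497) and without the filter (adjusted p = 0.0371). The list of other xenobiotic enzymes (18) rose in 10 treatments, 4 of them with an estimated correlation, the DNA repair list (29) in 9, 8 of them with an estimated correlation, and the matrix proteases (15) in 3 and the immediate early genes (27) in 6, 0 of either with an estimated correlation. Of the placental prolactin list 0 of 5 members passed the filter, so it was not tested.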

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

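The tests of time dependence and the regroupings of arrays were chosen before the results were seen, and the count of regroupings that keep a real grouping only after.

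For 5 treatments at 1 concentration the response differed between 24 h and 120 h by a test of the difference itself, in 1550 genes for 2 µM MCA, 366 for 0.5 µM BaP, 331 for 50 µM DAT, 5 for 10 µM AAF and 1 for 25 µM AAF, which was Cyp1a1. Treated and control arrays were regrouped within each time in 100 ways, the real one included. As many genes or more came from 3 of these for 2 µM MCA (highest other 1957), 8 for 0.5 µM BaP (highest other 1771), 14 for 50 µM DAT (highest other 709), 15 for 25 µM AAF (highest other 8) and 58 for 10 µM AAF (highest other 1713). For MCA, BaP and DAT all of these (3, 8 and 14) kept the real grouping at 120 h and so still held that response, and for 25 µM and 10 µM AAF 11 and 14 kept it at 24 h or 120 h. The shares therefore do not show whether chance can be excluded. Regroupings that kept the real grouping at neither time gave at most 2 genes for MCA, 0 for BaP, 0 for DAT and 6 for 25 µM AAF. For 10 µM AAF they gave up to 1713, which points to a structure of the samples. There 179 genes differed with the replicate block, 0 in a separate fit of approach 2 and 0 in a fit of these groups alone. For 25 µM AAF a fit of its groups alone also gave 0, so the Cyp1a1 call was lost.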

How the results depend on the processing

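Normalization over all 60 arrays, separate fits and leaving out the 3 arrays that stand apart were chosen after the results were seen, and the other settings before. Of the 878 values that the rule for named genes gave and that passed, 0 changed direction in any setting, 207 lost their call in some leave-out and 147 in a separate fit. The 189 given in the text, picked in part because they held, lost 14 and 6. Values that had not passed changed sign near 0, where Cyp1a1 with 1.5 µM BaP against 20 µM MCA at 24 h was -0.007 to 0.182 leaving out each array in turn and Cyp1a1 with 0.2 µM DAT at 120 h was -0.02 on deposited values and -0.156 to 0.18 leaving out each array in turn. Of 162 list calls 87 held with an estimated correlation, the setting that moved their number by over 1.5 times, and with the replicate number as a block 3 were lost and 8 gained. No list called in both of a pair of settings was called in the opposite direction. Dim signal limits what can be seen, since 12637 of 18194 genes passed the filter. The cause of the changes in count was not tested. The alternatives listed for the 7 comparisons across approaches were not run.

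With the replicate number as a block, 25 of 27 counts moved by over 1.5 times. The counts were 258 for 25 µM AAF at 24 h, 1181 for 0.5 µM BaP at 24 h, 86 for 50 µM DAT at 24 h and 316 for 2 µM MCA at 24 h. Then came 62 for 25 µM AAF at 120 h, 3191 for 0.5 µM BaP at 120 h, 2909 for 50 µM DAT at 120 h and 4668 for 2 µM MCA at 120 h. Next were 67 for 10 µM AAF at 24 h, 2360 for 1.5 µM BaP at 24 h, 4109 for 700 µM DAT at 24 h and 1994 for 20 µM MCA at 24 h. Counts were also 2066 for 10 µM AAF at 120 h, 2400 for 0.1 µM BaP at 120 h, 1128 for 0.2 µM DAT at 120 h and 2217 for 0.1 µM MCA at 120 h. BaP against MCA gave 431 at 24 h and 4945 at 120 h in approach 1, and 300 and 282 in approach 2. Time changes gave 7 for 25 µM AAF, 869 for 0.5 µM BaP, 807 for 50 µM DAT and 3010 for 2 µM MCA. That of 10 µM AAF gave 179. In the 6 comparisons whose numbers did not pair the arrays, the arrays that correlated best with their own number were 4 of 6 for 2 µM MCA at 24 h, 2 for 50 µM DAT at 120 h, 3 for 0.1 µM BaP and 3 for 0.2 µM DAT at 120 h, 4 for 0.5 µM BaP against 2 µM MCA at 24 h and 2 for the controls of approach 1.

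With a pseudocount of 1, 1 of 27 counts moved by over 1.5 times. The counts were 2 for time change of 25 µM AAF. With no filter on dim probe sets, 4 of 27 counts moved by over 1.5 times. The counts were 82 for 10 µM AAF at 24 h, 24 for 0.2 µM DAT at 120 h, 130 for 1.5 µM BaP against 20 µM MCA at 24 h and 49 for time change of 10 µM AAF. With deposited values without quantile normalization, 9 of 27 counts moved by over 1.5 times. The counts were 1 for 25 µM AAF at 24 h, 14 for 10 µM AAF at 24 h, 157 for 10 µM AAF at 120 h and 343 for 0.1 µM BaP at 120 h. There were 1 for 0.2 µM DAT at 120 h and 208 for time change of 50 µM DAT. BaP against MCA gave 53 at 24 h in approach 1, and 39 at 24 h and 32 at 120 h in approach 2.

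With only the groups of the contrast in the fit, 22 of 27 counts moved by over 1.5 times. The counts were 0 for 25 µM AAF at 24 h, 659 for 0.5 µM BaP at 24 h, 3 for 25 µM AAF at 120 h and 2942 for 0.5 µM BaP at 120 h. Next were 4903 for 2 µM MCA at 120 h, 3 for 10 µM AAF at 24 h, 78 for 1.5 µM BaP at 24 h and 562 for 700 µM DAT at 24 h. Counts were also 40 for 20 µM MCA at 24 h, 2 for 10 µM AAF at 120 h, 23 for 0.1 µM BaP at 120 h and 0 for 0.2 µM DAT at 120 h. There were 101 for 0.1 µM MCA at 120 h. BaP against MCA gave 224 at 24 h and 4971 at 120 h in approach 1, and 0 and 2 in approach 2. Time changes gave 0 for 25 µM AAF, 796 for 0.5 µM BaP, 682 for 50 µM DAT and 2997 for 2 µM MCA. That of 10 µM AAF gave 0. With quantile normalization over all 60 arrays, 7 of 27 counts moved by over 1.5 times. The counts were 23 for 25 µM AAF at 24 h, 29 for 25 µM AAF at 120 h, 5 for 10 µM AAF at 24 h and 4 for 0.2 µM DAT at 120 h. Next were 33 for 1.5 µM BaP against 20 µM MCA at 24 h, 2 for time change of 25 µM AAF and 1 for time change of 10 µM AAF. With a separate fit for each approach, 25 of 27 counts moved by over 1.5 times. The counts were 115 for 25 µM AAF at 24 h, 1190 for 0.5 µM BaP at 24 h, 22 for 50 µM DAT at 24 h and 281 for 2 µM MCA at 24 h. There were 45 for 25 µM AAF at 120 h, 3384 for 0.5 µM BaP at 120 h, 3001 for 50 µM DAT at 120 h and 4947 for 2 µM MCA at 120 h. Others were 3 for 10 µM AAF at 24 h, 303 for 1.5 µM BaP at 24 h, 992 for 700 µM DAT at 24 h and 166 for 20 µM MCA at 24 h. Further ones were 71 for 10 µM AAF at 120 h, 182 for 0.1 µM BaP at 120 h, 0 for 0.2 µM DAT at 120 h and 312 for 0.1 µM MCA at 120 h. BaP against MCA gave 387 at 24 h and 5264 at 120 h in approach 1, and 10 and 10 in approach 2. Time changes gave 7 for 25 µM AAF, 1075 for 0.5 µM BaP, 1037 for 50 µM DAT and 3560 for 2 µM MCA. That of 10 µM AAF gave 0. With the 3 arrays that stand apart left out, 5 of 14 counts moved by over 1.5 times. The count was 8 for 50 µM DAT at 24 h. Time changes gave 2 for 25 µM AAF, 190 for 0.5 µM BaP, 184 for 50 µM DAT and 732 for 2 µM MCA.

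Leaving out each array in turn moved some count by over 1.5 times in 18 of 27 comparisons. The ranges were 1 to 16 for 25 µM AAF at 24 h, 249 to 356 for 0.5 µM BaP at 24 h, 2 to 6 for 50 µM DAT at 24 h and 52 to 75 for 2 µM MCA at 24 h. Then came 2 to 39 for 25 µM AAF at 120 h, 11 to 27 for 10 µM AAF at 24 h, 512 to 764 for 1.5 µM BaP at 24 h and 368 to 568 for 20 µM MCA at 24 h. Next were 138 to 533 for 10 µM AAF at 120 h, 351 to 590 for 0.1 µM BaP at 120 h, 0 to 22 for 0.2 µM DAT at 120 h and 41 to 86 for 0.5 µM BaP against 2 µM MCA at 24 h. Counts were also 34 to 91 for 1.5 µM BaP against 20 µM MCA at 24 h, 34 to 51 for 0.1 µM BaP against 0.1 µM MCA at 120 h, 1 to 13 for time change of 25 µM AAF and 216 to 358 for time change of 0.5 µM BaP. There were 199 to 305 for time change of 50 µM DAT and 1 to 34 for time change of 10 µM AAF.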

Other observations

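The tests on normalization, on the exchange of arrays and on the control change of cell-cycle genes were chosen only after the results they concern were seen, and the others before.

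A few genes known from the early mouse embryo fell together in approach 2, among them Tcstv1, Zfp352 and Usp17la and the clone-named AF067061, BC080696 and Gm20767, which were picked because they fell. With 700 µM DAT at 24 h their median log2 change was -2.88 and 6 of 6 were called lower. At 120 h the medians were -1.11 with 10 µM AAF, -1.60 with 0.1 µM BaP and -1.68 with 0.1 µM MCA, again with 6 called lower in each, and -0.55 with 0.2 µM DAT, where 0 were called. With 10 µM AAF, 1.5 µM BaP and 20 µM MCA at 24 h the medians were 0.12, -0.14 and -0.46, with 0, 0 and 1 called lower. The controls changed the same way over time, with medians of -2.36 (5 called lower) in approach 1 and -1.44 (6 called lower) in approach 2.

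Normalization between arrays does not account for the fall, since the median with 700 µM DAT was -2.75 on deposited values. Whether a wider early-embryo program moved could not be told, because only 1 further listed member passed the filter, at -0.41. Cross-hybridisation between these related, repetitive genes was not tested, and a biological explanation by the treatment stays open.

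At 120 h the mitosis list stood above the controls with 0.5 µM BaP, 50 µM DAT and 2 µM MCA in approach 1. In approach 2 its median was below them with 10 µM AAF and, in calls lost with an estimated correlation (adjusted p = 0.167 and 0.102), with 0.1 µM BaP and 0.1 µM MCA, while with 25 µM AAF in approach 1 0 of 29 members passed. On deposited values the lowest mitosis median of approach 1 (50 µM DAT, 0.87) exceeded the higher one of 0.1 µM BaP and 0.1 µM MCA by 1.09, which argues against normalization between arrays. One candidate explanation is a deeper fall of cell-cycle genes in the controls of approach 1, whose mitosis median changed by -0.47 more between 24 h and 120 h (-2.24 against -1.77, with an SD between genes of 0.17 and 0.21). A change of that size would cover only part of the 1.09. The comparison of the controls lies across separately scaled tables and the concentrations differed as well, so the concentration stays open and untested.

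Pde6b parted arrays of 1 group in approach 1, with deposited intensities of 47.1, 29.2 and 0.7 in the 24 h controls, 6, 228.7 and 185.8 in the 120 h controls and 4.5, 2.1 and 45.6 with 2 µM MCA at 24 h, and AI662270 (65.3, 145.8 and 144.5) and Gnpda2 (139.9, 261.6 and 283), chosen after their values were seen, parted the 120 h controls alike. With 0.5 µM BaP all 6 arrays were high (Pde6b 32.4 to 104.8, AI662270 153.4 to 209.9), while with 25 µM AAF, with 50 µM DAT and with 2 µM MCA at 120 h all were low (Pde6b at most 6.7, AI662270 at most 79.3), so these levels also ran along the compound and comparisons of those groups hold them. An exchange of 2 µM MCA and control arrays at 24 h is excluded by Cyp1a1, whose lowest array with 2 µM MCA exceeded the highest control by 4.80 on the log2 scale. Cyp1a1 gaps of at least 1.727 also exclude exchanges of 50 µM DAT arrays with controls of the same time and of 25 µM AAF arrays with controls at 120 h. The same holds for either compound with MCA arrays at 24 h. For 25 µM AAF and controls at 24 h the gap of 0.354 (larger SD 0.239) was too small to exclude an exchange. A difference in RNA quality was not decided, since by the Gapdh ratio 2 of the 3 arrays lay inside the range of the others and 1 at its edge, outside by less than the printed digits (-0.252 for both), and the deviations of the 3 arrays from their groups correlated at -0.383, -0.175 and -0.119 across genes. No biological explanation was tested.

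Arrays of each comparison of 3 against 3 can be grouped in 10 ways, too few for a share under 0.05. The real grouping and the highest other called 12 and 0 for 25 µM AAF at 24 h, 374 and 0 for 0.5 µM BaP at 24 h, 3 and 0 for 50 µM DAT at 24 h and 89 and 1 for 2 µM MCA at 24 h. Further ones were 12 and 9 for 25 µM AAF at 120 h, 1672 and 0 for 0.5 µM BaP at 120 h, 1269 and 1 for 50 µM DAT at 120 h and 2906 and 2 for 2 µM MCA at 120 h. Then came 821 and 41 for 1.5 µM BaP at 24 h, 2105 and 67 for 700 µM DAT at 24 h, 588 and 97 for 20 µM MCA at 24 h and 604 and 442 for 0.1 µM BaP at 120 h. Next were 89 and 0 (24 h) and 3129 and 0 (120 h) for 0.5 µM BaP against 2 µM MCA. The controls gave 5494 and 1 in approach 1 and 6374 and 1428 in approach 2. In these the real grouping gave the most. In others a different grouping gave more. They were 22 and 46 for 10 µM AAF at 24 h (4 of 10 as large), 367 and 808 for 10 µM AAF at 120 h (2 of 10 as large), 8 and 119 for 0.2 µM DAT at 120 h (3 of 10 as large) and 734 and 1475 for 0.1 µM MCA at 120 h (2 of 10 as large). There were 69 and 109 for 1.5 µM BaP against 20 µM MCA at 24 h (2 of 10 as large) and 54 and 269 for 0.1 µM BaP against 0.1 µM MCA at 120 h (4 of 10 as large). Where the numbers pair the arrays, the 3 other groupings that part all 3 pairs called at most 5, 3, 10 and 17 genes for 10 µM AAF, 1.5 µM BaP, 700 µM DAT and 20 µM MCA at 24 h, and 2 and 2 for 10 µM AAF and 0.1 µM MCA at 120 h. The groupings with many genes kept 2 pairs together, which points to a structure that follows the replicate number.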
